A study of Mus musculus with 46 samples.

How the data were processed

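RNA sequencing libraries were made from the right striatum and the cerebral cortex of 23 mice, 1 library per tissue and animal, 46 libraries in all. The animals were 8 wild-type (WT) mice given vehicle, 7 R6/2 mice given vehicle and 8 R6/2 mice given the kynurenine 3-monooxygenase (KMO) inhibitor CHDI-00340246, as the labels state. R6/2 mice carry exon 1 of the human huntingtin gene with an expanded CAG repeat and are a model of Huntington's disease. Dosing was oral, 30 mg/kg twice-daily, from 4 to 12 weeks of age. The WT and the treated groups held 4 females each, and the vehicle R6/2 group held 3 males beside 4 females. No WT mouse received the compound, so the compound was compared with vehicle in R6/2 mice alone. Animal codes in the labels show which striatal and cortical libraries came from 1 mouse. Per the labels' protocols, tissue was flash frozen, total RNA was extracted with a miRNeasy kit and an enriched fraction went into Illumina libraries; how the fraction was enriched and whether the libraries kept strand are not given in the sources used here. Reads from a gene and its antisense partner therefore cannot be told apart.

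The authors deposited 1 table of estimated counts and 1 table of FPKM values, each with 43346 Ensembl genes and all 46 libraries. The submitters' processing notes name CASAVA 1.8.2 and the genome build mm10; the aligner, the quantifier and the annotation are not given in the sources used here. Of the nonzero values in the deposited count table, a share of 33.8% was not whole (tolerance 1e-06), so these are estimated counts, in which reads shared by similar genes can be split; they were rounded to whole numbers before any test. The deposited FPKM values are scaled to transcript length and library size by the authors, with a denominator that is not stated. Gene symbols came from a reference table that matched 42462 of the genes (98.0%); genes without a symbol kept their Ensembl identifiers and held 0.166% of the counts. Of all genes, 13235 had no count in any library. The 37 mitochondrial genes are listed with no count at all, and 6 unprocessed pseudogenes that copy mitochondrial sequence held between 3.73% and 8.85% of a library's counts. Positions are those of GENCODE vM21 on mm10.

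Total counts per library, in units of 1e+06, ran from 30.4 to 36.0 in the striatum and from 31.8 to 37.8 in the cortex. The 20 highest genes held 7.48% to 12.8% of the counts in the striatum and 7.25% to 10.0% in the cortex. With 23 libraries per tissue the median standard error of a log2 fold change was 0.086 for both R6/2 comparisons in the striatum and 0.089 in the cortex. Reads carry no molecular identifiers, so the tests rest on the spread between animals and not on counting error. Labels were checked against genes with known behaviour. For these checks CPM are counts per 1e+06, TMM-scaled over all 46 libraries. Xist was at least 750 CPM in every library labelled female and at most 2.91 CPM in every library labelled male. Ddx3y was at least 65.8 CPM in males and at most 0.0951 CPM in females. Drd2 was at least 19.1 CPM in every striatal library and at most 3.41 CPM in every cortical library. Gm12695, the gene of the mouse genome recorded at the R6/2 insertion site, was at least 2.57 CPM in all R6/2 libraries and at most 0.158 CPM in all WT libraries. No pair of libraries of 1 group agreed within sampling noise: the lowest chi-square per degree of freedom over genes was 7.72.

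Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was edgeR's quasi-likelihood test on rounded counts with TMM scaling and the filterByExpr filter, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each tissue was fitted apart with all 3 groups and sex as a covariate, which left 19 residual degrees of freedom, and 17394 genes were tested in the striatum and 17484 in the cortex. In each tissue vehicle R6/2 was compared with WT, treated R6/2 with vehicle R6/2, and treated R6/2 with WT, and the first 2 of these effects were compared between females and males by interaction. Effects were compared between tissues by interaction in 1 fit of all 46 libraries with the animal as a block (18122 genes), and striatum with cortex in the 16 WT libraries with the animal as a block (17051 genes). Standard errors (SE) are the log2 fold change divided by the square root of the test's F value. CPM values are TMM-scaled means ± SD over animals.

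Whether treatment moved the disease profile as a whole was tested with 1 score per animal. The score used the genes called between WT and all 15 R6/2 animals pooled, each weighted by its log2 difference from WT on log2 CPM with a prior count of 2, so that 0 is the WT mean and about 100 the R6/2 mean. Treated and vehicle animals entered the choice of genes and weights alike, and their scores were compared by an exact two-sided permutation test over all 6435 splits of the 15 animals. Overlap of the R6/2 comparisons, which share the WT libraries, was set beside the count that independent lists give, beside 20 simulations of unchanged groups and beside 10 splits of the WT libraries into 4 and 4.

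The gene lists, 31 in all, were written down in advance. They cover the kynurenine pathway, nicotinamide adenine dinucleotide (NAD) metabolism and aryl hydrocarbon receptor targets; striatal projection neurons in general and of the direct (D1) and indirect (D2) pathway; cortical projection neurons and interneurons; astrocytes, reactive astrocytes, microglia, myelinating oligodendrocytes, oligodendrocyte precursors, endothelium with pericytes, choroid plexus with ependyma, blood, and regions next to the dissected tissue; and immediate-early genes, interferon and cytokine response, cholesterol synthesis, heat shock, oxidative phosphorylation, developmental transcription factors, glutamate receptors, GABA receptors, potassium channels, the Nrf2 oxidative response, the integrated stress response, circadian clock genes and glucocorticoid targets, with sex-linked and transgene genes as label checks. The 30 lists other than the label checks were tested with limma's camera on log2 CPM with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. Members were counted with p adjusted over all genes tested and adjusted over the list alone.

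Genes are named by a fixed rule: the 8 called genes with the largest change in each direction at a mean of at least 1 CPM and with a regular symbol; up to 4 called members of smallest adjusted p per list, or 2 uncalled ones; every kynurenine pathway member; the label checks; where nothing was called, the 4 genes of smallest p in each direction; and 5 genes per direction for the interactions. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, unless the text says otherwise. The design had foreseen whole counts; the deposited values turned out to be estimated counts and were rounded, with the test kept.

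Alternatives to the main settings were DESeq2 size factors, no filter and a filter of 1 CPM in 7 libraries, DESeq2's Wald test, limma-voom with quality weights, limma on log2 of FPKM plus 0.1 or plus 1, no sex term, the replicate number of the titles as a block, the run tag of the library names as a covariate, only the groups compared, and each library or animal left out in turn. For the lists each R6/2 library was left out in turn for treated against vehicle mice, a choice made after seeing the data. The run tags (8, L1 to L8) are part of the library names and their meaning is not given; they do not divide evenly over the groups. Libraries of the same animal from the 2 tissues deviated from their group means together, with a correlation across genes of 0.218 to 0.626 (median 0.408) in 23 of 23 animals, and for 22 of 23 striatal libraries the cortex library of the same animal was the best match, so the animal was kept as the block between tissues. The fits were tested on simulated counts in which 200 genes were changed. For treated against vehicle R6/2 mice, 43.3%, 70.1% and 84.8% of genes changed 1.25-, 1.5- and 2-fold were called in the striatum, with 13 false calls, and 38.8%, 64.2% and 86.4% in the cortex, with 4. For the difference of the drug effect between sexes the shares at 2-fold were 65.2% and 56.1%, and for its difference between tissues 80.3%. The simulation between tissues used a preset dispersion and a preset spread between animals, not values estimated from the data. Its 80.3% therefore does not give the sensitivity of that test in these data. A simulated reduction of the disease profile by 10% was read as -9.55 points in the striatum and -8.82 points in the cortex, each with an exact permutation p of 0.000155, the smallest that 6435 splits can give. Genes were drawn independently here, without variation shared over genes within an animal. The simulated 95% interval in the striatum, -10.3 to -8.78, was narrower than that of the real scores, -2.24 to 6.89. The simulation therefore does not give the sensitivity of the score in these data.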

Results

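The striatum and cortex of 12-week-old mice were sequenced to ask which genes differ in R6/2 mice, a model of Huntington's disease. A further question was whether 8 weeks of a KMO inhibitor altered them. KMO converts kynurenine, a product of tryptophan breakdown, to 3-hydroxykynurenine, and in brain it is found mainly in microglia. Each tissue had 8 WT vehicle, 7 R6/2 vehicle and 8 R6/2 treated libraries from the same 23 animals. Depth, in units of 1e+06 counts per library, was 30.5 to 35.1 in WT, 30.4 to 36.0 in vehicle and 32.3 to 35.6 in treated striatum. In the cortex it was 32.7 to 37.0, 31.9 to 37.8 and 31.8 to 37.6.

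In the striatum of vehicle R6/2 mice the genes that define striatal projection neurons, the main cell type of that region, were lower. Ryr1, a calcium release channel on chromosome 7, was 14.8-fold lower, from 142 ± 24 CPM in WT (SD, n = 8) to 9.57 ± 1.75 CPM (n = 7; log2 -3.89 ± 0.14 SE, adjusted p = 4.02e-15). The sodium channel subunit Scn4b fell by 3.09 ± 0.26 on the log2 scale, the cannabinoid receptor Cnr1 by 2.04 ± 0.09, and the exchange factor Rasgrp2 by 1.81 ± 0.14. Of the 23 listed genes of striatal projection neurons 22 were lower and 0 higher, over all genes and adjusted over the list alone. Their median was -1.34 (camera adjusted p = 2.42e-10; adjusted p = 0.256 with an estimated correlation).

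In the indirect pathway list Penk, the precursor of enkephalin, averaged 358 ± 27.2 CPM in vehicle R6/2 mice (log2 -2.04 ± 0.14 against WT). The adenosine receptor Adora2a fell by 1.79 ± 0.21, the orphan receptor Gpr6 by 1.47 ± 0.20 and the dopamine receptor Drd2 by 1.29 ± 0.18. There 5 of 6 tested genes were lower (5 adjusted over the list alone; median -1.38; camera adjusted p = 0.00355, and adjusted p = 0.37 with an estimated correlation). In the direct pathway list the muscarinic receptor Chrm4 fell by 1.58 ± 0.11 and the dopamine receptor Drd1 by 1.31 ± 0.16, while the transcription factors Eya1 (0.60 ± 0.14) and Isl1 (0.34 ± 0.07) rose. In that list 3 of 7 genes were higher and 3 lower by both adjustments, and it was not called (adjusted p = 0.582).

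**Figure D1:**
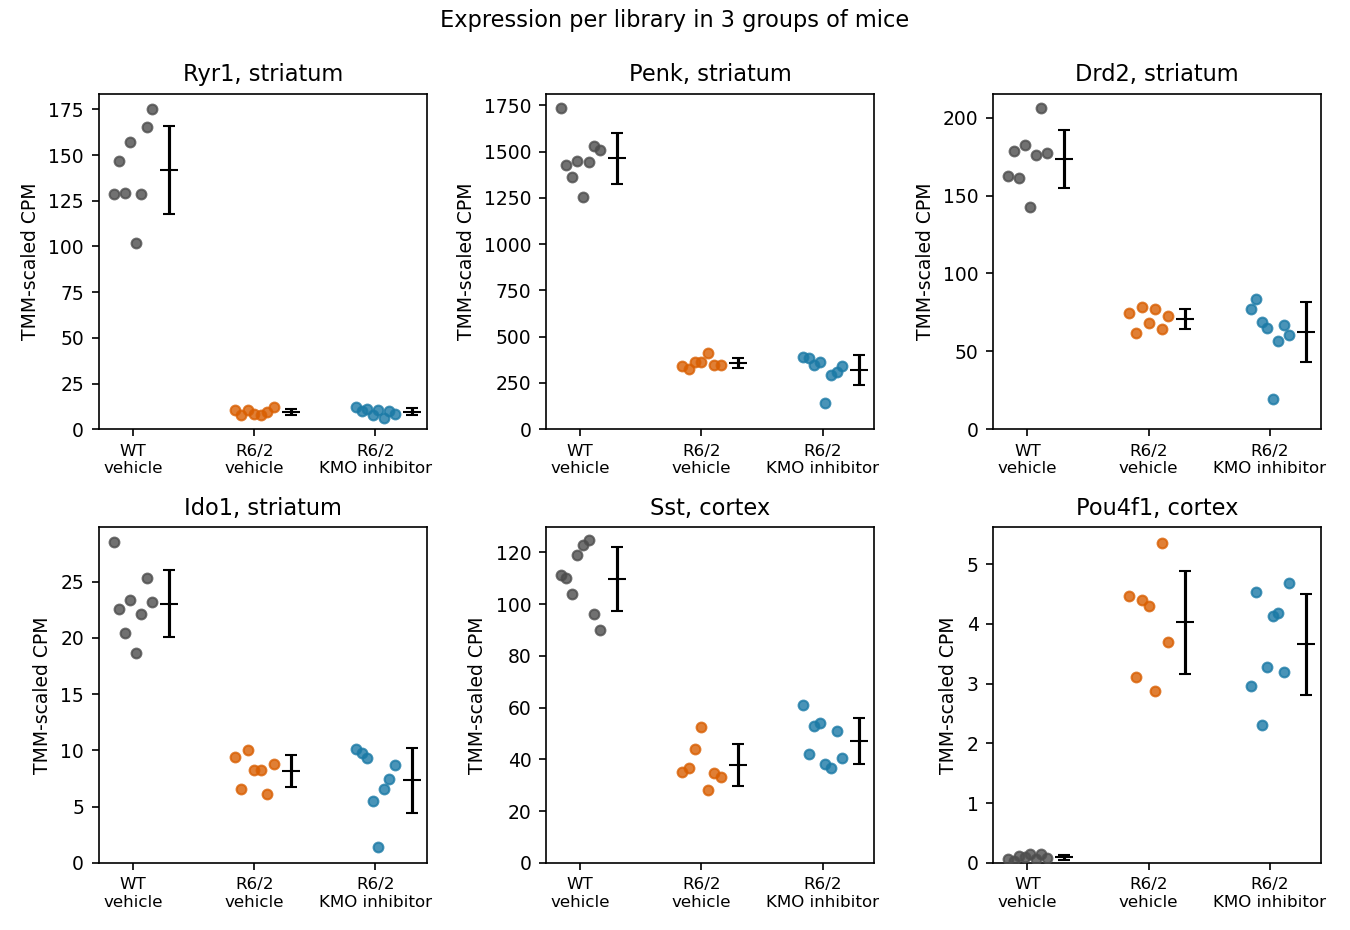
TMM-scaled CPM (vertical axes) of 4 genes in the striatum and 2 in the cortex for WT vehicle, R6/2 vehicle and R6/2 treated mice; each point is 1 library, and the bars to the right give mean ± SD. Vehicle and treated R6/2 libraries lie together and apart from WT for Ryr1, where the means were 9.57 and 9.52 CPM against 142 CPM in WT, and treated striatal replicate 5 is the lowest point for Penk and Drd2.

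The 8 largest increases and decreases in the striatum were spread over other functions. The transcription factor Wt1 rose 13.6-fold, from 0.113 to 1.63 CPM (log2 3.76 ± 0.24), and Zfhx2os by 3.83 ± 0.32 on the log2 scale. Further increases were in the B cell receptor gene Tnfrsf13c (2.66 ± 0.27), the noncoding RNA Crnde (2.08 ± 0.17), the small membrane protein gene Smim24 (2.02 ± 0.16), the desmosomal genes Dsp (2.00 ± 0.35) and Ppl (1.85 ± 0.25), and the spindle factor Tpx2 (1.85 ± 0.12). Beside Ryr1 the largest decreases were in Gpx6, a glutathione peroxidase (-5.20 ± 0.24, from 6.80 to 0.181 CPM), the lipid transfer gene Sec14l3 (-4.97 ± 0.51) and Abhd11os (-4.61 ± 0.24). They were followed by the immediate-early transcription factor Egr2 (-3.62 ± 0.33), the complexin Cplx3 (-3.58 ± 0.28), the copine Cpne9 (-3.58 ± 0.40) and the receptor Mas1 (-3.44 ± 0.32). Zfhx2os and Abhd11os overlap or adjoin other genes, and reads were not assigned by strand as far as is known, so their values may include the partner's reads.

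Cell type lists in the R6/2 striatum moved down more often than up. Cholinergic genes led the interneuron list, with the choline acetyltransferase Chat (-1.81 ± 0.08), the choline transporter Slc5a7 (-1.57 ± 0.05) and the vesicular transporter Slc18a3 (-1.39 ± 0.15) lower. In that list 13 of 16 interneuron genes were lower and 0 higher by both adjustments (median -0.91, adjusted p = 4.05e-06, and 0.0157 with an estimated correlation). Astrocyte genes were lower in 12 of 13 and higher in 1, among them the glutamate transporter Slc1a2 (-0.96 ± 0.09) and Aldoc (-0.74 ± 0.07), with the same counts adjusted over the list alone (adjusted p = 1.5e-05, and adjusted p = 0.151 with an estimated correlation). Myelin genes were lower in 9 of 15 cases by both adjustments, with Mal at -0.92 ± 0.10 and Fa2h at -0.81 ± 0.10 (adjusted p = 0.000248; adjusted p = 0.481 with an estimated correlation). Endothelial and pericyte genes were lower in 15 of 16 by both adjustments, with Esam at -0.41 ± 0.07 (adjusted p = 0.000138; adjusted p = 0.256 with an estimated correlation). Microglial genes were lower in 9 of 18 and higher in 1 (10 and 1 adjusted over the list alone), with Cx3cr1 at -0.30 ± 0.06 (adjusted p = 0.0399; adjusted p = 0.595 with an estimated correlation). Their median was -0.23, and -0.08 on log2 FPKM plus 0.1 (-0.23 and -0.20 relative to all genes), where limma no longer called Aif1, Gpr34 and P2ry12 (adjusted p 0.0613 to 0.262). All 5 tested blood genes were lower by both adjustments, with the globin Hbb-bs at -1.13 ± 0.17 (adjusted p = 0.00314; adjusted p = 0.256 with an estimated correlation), and the globin genes are near-identical pairs among which reads can be split. The share of counts on mitochondrial copies was 6.16 ± 1.15% in WT (n = 8) and 5.18 ± 0.484% in vehicle R6/2 striatum (n = 7).

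Signalling and metabolic lists were also called as groups, though with the preset correlation alone. Immediate-early genes, which respond to neuronal activity, were lower in 15 of 19 by both adjustments, with Homer1 at -1.10 ± 0.13 and Egr1 at -1.08 ± 0.18 (median -0.75; adjusted p = 0.000108, and adjusted p = 0.256 with an estimated correlation). Cholesterol synthesis genes were lower in 17 of 21, with Msmo1 at -1.15 ± 0.08 and Idi1 at -0.85 ± 0.09 (17 lower and 1 higher adjusted over the list alone; adjusted p = 1.58e-06, and adjusted p = 0.256 with an estimated correlation). Circadian clock genes were lower in 12 of 16 and higher in 2 by both adjustments, with the output factor Dbp at -1.33 ± 0.10 and Ciart at -1.18 ± 0.10 (adjusted p = 2.55e-05, and adjusted p = 0.256 with an estimated correlation). Potassium channel genes were lower in 19 of 26, led by Kcnh4 (-2.47 ± 0.20), and glutamate receptor and scaffold genes in 11 of 20, led by Shank3 (-1.15 ± 0.10), with the same counts adjusted over the list alone. Their adjusted p were 7.49e-06 and 5.54e-05, and for both adjusted p = 0.256 with an estimated correlation. Interferon and cytokine genes were higher in 13 of 15 by both adjustments, with Irf7 at 1.60 ± 0.29 (median 0.84; adjusted p = 0.000108, and adjusted p = 0.481 with an estimated correlation). Of 17 listed developmental transcription factors 3 passed the expression filter and were tested, and 2 of them were called by both adjustments. Pou4f1 rose from 0.0540 to 1.05 CPM (4.22 ± 0.48) and Onecut1 from 0.103 to 1.04 CPM (3.28 ± 0.35). Genes this low in WT pass the filter only through R6/2 libraries, so the share that rose does not describe the list.

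The remaining striatal lists were not called as groups and held single called genes. Cortical projection neuron genes were 2 higher and 5 lower of 15 (adjusted p = 0.323), with Crym at -1.22 ± 0.15. Listed genes of neighbouring regions were lower in 5 of 8 (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.0588), with the thalamic marker Prkcd at -2.06 ± 0.48. GABA receptor genes were 2 higher and 3 lower of 16 (adjusted p = 0.719), with the delta subunit Gabrd at -1.82 ± 0.18. Heat shock genes were 8 higher and 1 lower of 15 (adjusted p = 0.168), with Hspa5 at 0.46 ± 0.08. Reactive astrocyte genes were 3 higher and 1 lower of 15 (adjusted p = 0.91), with Vim at 0.57 ± 0.07. Oxidative phosphorylation genes were 1 higher and 7 lower of 23 (adjusted p = 0.462), with Ndufs3 at -0.29 ± 0.05, and NAD metabolism genes 3 higher and 6 lower of 15 (adjusted p = 0.462), with Sirt1 at 0.37 ± 0.06. Nrf2 genes were 1 higher and 3 lower of 13 (adjusted p = 0.719). Integrated stress response genes were 4 and 4 of 12 (adjusted p = 0.91), with Trib3 at -1.43 ± 0.21. Glucocorticoid targets were 1 and 3 of 11 (adjusted p = 0.421), with Mt2 at -0.91 ± 0.15. Oligodendrocyte precursor genes were 2 and 2 of 9 (adjusted p = 0.826), with Enpp6 at 0.69 ± 0.12. Choroid plexus and ependymal genes were 0 and 1 of 14 (adjusted p = 0.719). Aryl hydrocarbon receptor genes were 1 and 2 of 6 (adjusted p = 0.989) with Ahrr at 0.89 ± 0.15. In the lists of this paragraph other than the neighbouring regions the counts were equal when adjusted over the list alone.

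Across all genes, edgeR's quasi-likelihood test called 8735 of 17394 between vehicle R6/2 and WT striatum (50.2%), 4480 higher and 4255 lower. Of 920 called genes at 2-fold or more 209 were higher. On log2 FPKM plus 0.1, which moved the median of all genes by 0.122, limma called 6937 higher and 2727 lower. With the run tag as a covariate the count was 7930. As a check of the genotype label Gm12695 was 3.87 ± 0.381 CPM in vehicle R6/2 and 0.0862 ± 0.0497 CPM in WT (log2 5.43 ± 0.19). Endogenous Htt differed by 0.21 ± 0.08 (adjusted p = 0.0424), a call that was lost without any 1 of vehicle replicates 1, 3, 6 and 7 or WT replicates 5 and 6 (adjusted p 0.0560 to 0.0961), and the transgene's exon 1 reads may be counted in it. The call was also lost with the run tag as a covariate (adjusted p = 0.0773) and with DESeq2's size factors (adjusted p = 0.0507).

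In the cortex of vehicle R6/2 mice interneuron genes were lower, and some transcription factors of other lineages were higher. Pou4f1, a POU-domain factor of sensory neurons, rose 42.3-fold, from 0.0923 ± 0.0443 to 4.03 ± 0.863 CPM (log2 5.40 ± 0.24, adjusted p = 5.45e-14). Pax2 (3.47 ± 0.28), Twist1 (3.30 ± 0.22) and Onecut2 (2.36 ± 0.11) rose with it. Of 17 listed developmental factors 5 passed the expression filter and 4 of these were called higher by both adjustments. As in the striatum, members near 0 in WT pass only through R6/2 libraries. Interneuron genes fell, Sst from 110 ± 12.5 to 37.8 ± 8.04 CPM (log2 -1.55 ± 0.13), the synthesis enzyme Gad1 by 1.14 ± 0.09 and Npy by 1.27 ± 0.09. Of the list 13 of 16 interneuron genes were lower by both adjustments (median -0.70; adjusted p = 9.8e-07, and 0.00217 with an estimated correlation).

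Neuronal signalling lists of the cortex were lower too. Potassium channel genes were lower in 18 and higher in 1 of 26 by both adjustments, with Kcnh4 at -2.76 ± 0.22, Kcnh3 at -1.56 ± 0.11 and Kcnip2 at -1.47 ± 0.10 (adjusted p = 9.8e-07, and 0.0438 with an estimated correlation). Cortical projection neuron genes were lower in 9 of 15 and higher in 1 (2 higher adjusted over the list alone), with Nrn1 at -1.16 ± 0.10 and Rasgrf2 at -1.14 ± 0.06 (adjusted p = 0.00183; adjusted p = 0.143 with an estimated correlation). Genes listed for striatal projection neurons, many of which cortical neurons also express, were lower in 13 and higher in 1 of 23 (14 lower adjusted over the list alone), with Scn4b at -2.78 ± 0.19 and Ryr1 at -2.42 ± 0.18 (adjusted p = 4.3e-06; adjusted p = 0.084 with an estimated correlation). Glutamate receptor genes were lower in 9 of 20, with Grm2 at -1.35 ± 0.12, and GABA receptor genes in 7 of 16 (8 adjusted over the list alone), with Gabrd at -1.89 ± 0.12. Their adjusted p were 0.00384 and 0.00931, and for both adjusted p = 0.164 with an estimated correlation. Immediate-early genes were lower in 15 of 19 by both adjustments, with Egr2 at -3.40 ± 0.47 and Fosl2 at -1.47 ± 0.16 (median -0.98; adjusted p = 3.7e-05, and adjusted p = 0.209 with an estimated correlation).

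Metabolic, glial and immune lists of the cortex followed. Cholesterol synthesis genes were lower in 19 of 21 by both adjustments, with Insig1 at -0.82 ± 0.10 (adjusted p = 4.52e-07; adjusted p = 0.164 with an estimated correlation). Clock genes were lower in 13 and higher in 2 of 16 by both adjustments, with Ciart at -1.39 ± 0.12 and Dbp at -1.33 ± 0.08 (adjusted p = 2.14e-06; adjusted p = 0.084 with an estimated correlation). Astrocyte genes were lower in 11 of 13 by both adjustments, with Aldoc at -0.88 ± 0.08 (adjusted p = 1.11e-06; adjusted p = 0.0882 with an estimated correlation). Reactive astrocyte genes were higher in 7 of 16 by both, with Psmb8 at 0.74 ± 0.14 and Vim at 0.65 ± 0.12 (adjusted p = 0.0492; adjusted p = 0.549 with an estimated correlation). Interferon and cytokine genes were higher in 13 of 16 (15 adjusted over the list alone), with Usp18 at 1.86 ± 0.25 and Irf7 at 1.85 ± 0.21 (median 0.99; adjusted p = 5.24e-07, and adjusted p = 0.188 with an estimated correlation). Myelin genes were lower in 8 of 15 by both adjustments, with Fa2h at -0.54 ± 0.12 (adjusted p = 0.0285; adjusted p = 0.714 with an estimated correlation). All 5 blood genes were lower, with Hbb-bs at -0.90 ± 0.14 (adjusted p = 0.00415; adjusted p = 0.209 with an estimated correlation). The other 15 lists were not called in the cortex.

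**Figure D2:**
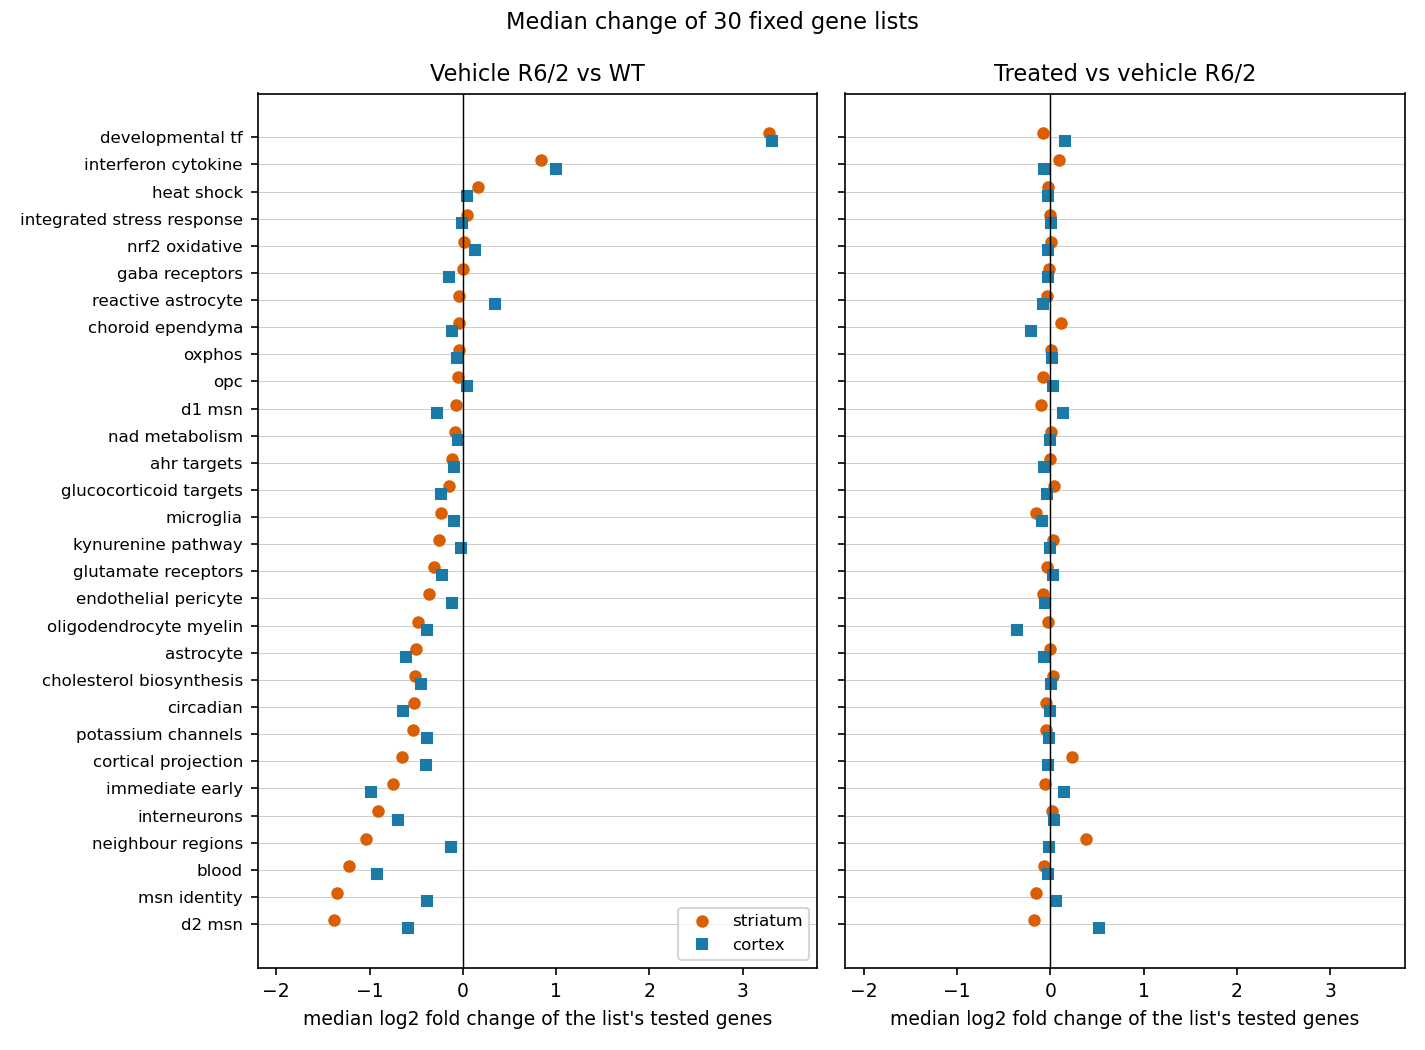
Median log2 fold change (horizontal axes) of the tested genes of 30 fixed lists, for vehicle R6/2 against WT on the left and treated against vehicle R6/2 on the right; circles are striatum, squares cortex. Apart from developmental factors, of which the filter kept 3 and 5 of 17, the disease median furthest from 0 is -1.38 for striatal indirect pathway genes, while the drug medians lie between -0.35 and 0.53.

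Other large changes in the R6/2 cortex included the signalling regulator Rgs13 (3.78 ± 0.30) and Crnde (2.65 ± 0.25) among the increases. Decreases included the lipoxygenase Alox12b (-4.54 ± 0.20), the kinase Plk5 (-4.13 ± 0.33), Sytl1 (-4.07 ± 0.45), the protease Adam33 (-3.83 ± 0.29) and the keratin Krt80 (-3.22 ± 0.22). The rule also names 4 genes whose calls were lost without single libraries. The pituitary hormones Prl (-5.76 ± 2.06, adjusted p = 0.0259) and Gh (-5.24 ± 1.98, adjusted p = 0.0345) averaged 13.5 ± 36.8 and 6.15 ± 15.6 CPM in WT, where WT replicate 8 held 104.7 and 44.6 CPM. Without it Prl was at -1.71 (adjusted p = 0.409), and no value for Gh is available. Both calls were also lost without any 1 of vehicle replicates 1, 3, 4 and 5, and for Gh 6 and 7 (adjusted p 0.0520 to 0.0726). The receptor gene Pgr15l (4.60 ± 1.35) was at 1.99 (adjusted p = 0.169) and the glycine transporter Slc6a5 (2.68 ± 1.05) at 0.79 (adjusted p = 0.515) without vehicle replicate 4, and Slc6a5 also lost its call without any 1 of WT replicates 1 to 7 (adjusted p 0.0555 to 0.0767). With the run tag as a covariate Gh and Slc6a5 were not called (adjusted p = 0.0558 and 0.0534).

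In all, 7712 of 17484 genes were called between vehicle R6/2 and WT cortex (44.1%; edgeR), 3753 higher and 3959 lower, and 189 higher and 647 lower at 2-fold or more. On log2 FPKM plus 0.1 limma called 5469 higher and 2992 lower. The WT libraries carried run tags L7 and L8 alone, which 4 vehicle libraries shared; within these tags 7399 genes were called, and 6545 with the tag as a covariate. Gm12695 was 3.22 ± 0.339 CPM in vehicle R6/2 and 0.0396 ± 0.0429 CPM in WT cortex.

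Striatum and cortex shared much of the disease profile, but 2862 of 18122 genes differed in effect between them. This was edgeR's interaction within animals, with 1279 more positive and 1583 more negative effects in the striatum. Striatal and cortical libraries of WT or vehicle R6/2 mice shared no run tag. The tag was not fitted in this comparison, so differences that follow it cannot be told apart. Cnr1 fell by 2.04 in the striatum and measured -0.13 in the cortex (interaction -1.93 ± 0.11, adjusted p = 2.01e-11), and the kainate receptor Grik2 fell by 1.09 against 0.05 in the cortex (-1.16 ± 0.09). The citrate lyase Acly (-0.68 against 0.04; interaction -0.75 ± 0.05), the phosphodiesterase Pde1c (-0.41 against 0.63; -1.06 ± 0.07) and Onecut2 (0.24 against 2.36; -2.14 ± 0.16) also had the more negative effect in the striatum. The opposite held for Ipcef1 (1.26 in striatum against -0.58 in cortex; interaction 1.82 ± 0.12) and Phf21b (0.03 against -1.44; 1.46 ± 0.09). It also held for the kinases Nlk (0.09 against -0.75; 0.80 ± 0.05) and Pak1 (0.23 against -0.64; 0.85 ± 0.06), and Tcf19 (0.41 in striatum; 1.38 ± 0.10).

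**Figure D3:**
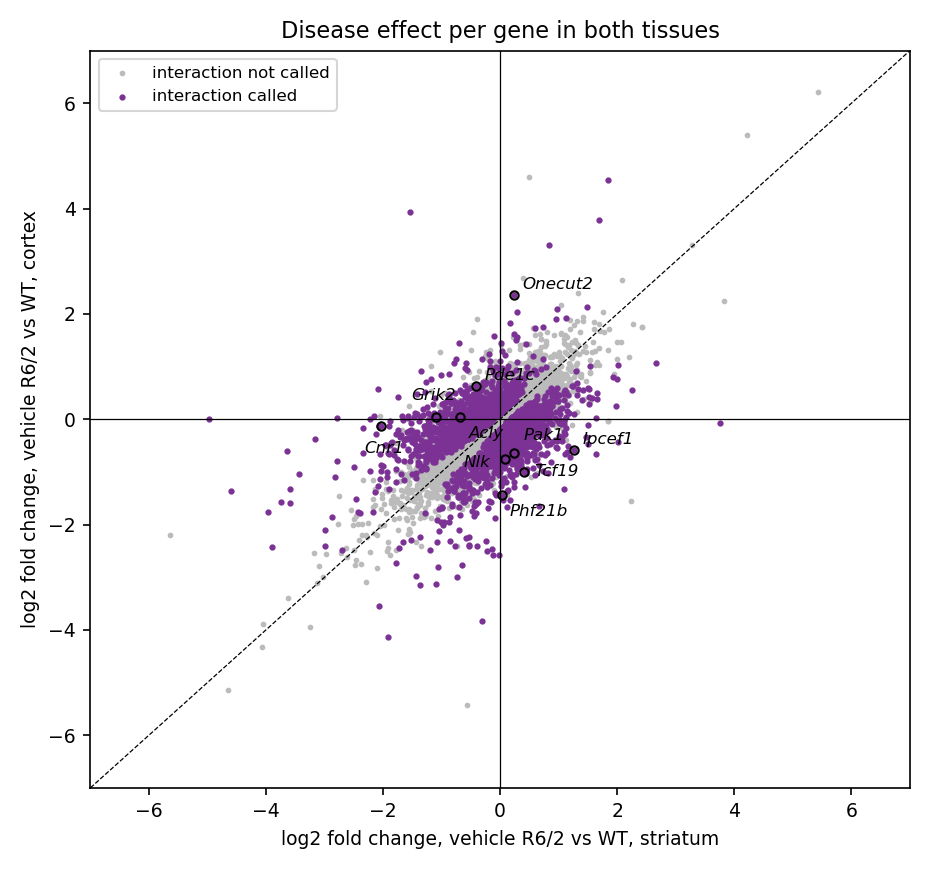
Log2 fold change of vehicle R6/2 against WT for each gene in the striatum (horizontal axis) and in the cortex (vertical axis); purple points were called in the interaction of tissue and disease, and the 10 named genes are circled. Most genes lie along the dashed line of equal change (Pearson r = 0.69 across genes), and Cnr1, Grik2, Onecut2 and Ipcef1 lie far from it.

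Of 16964 genes tested in both tissues, 2685 were higher in both and 2460 lower in both, against 970 and 919 that independent lists give. Opposite calls were made for 219 genes, all of which were also called in the interaction. The fold changes correlated with a Pearson r of 0.69 and a Spearman rho of 0.687 across genes, which are not independent replicates, and the same animals gave both tissues. Genes with regional expression were lower more often in their own region. WT striatum and cortex differed in 10708 of 17051 genes (edgeR, animal as a block; 5316 higher in striatum), and of 1038 genes at least 2-fold higher in WT striatum 57.5% were lower in R6/2 striatum, against 25.1% of 890 in R6/2 cortex. Of 1216 genes at least 2-fold higher in WT cortex 56.8% were lower in R6/2 cortex, against 25.1% of 1045 in R6/2 striatum. The enriched genes were chosen on the same WT libraries that enter the disease comparison. WT striatum and WT cortex shared no run tag, so tag and tissue cannot be told apart in that choice.

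Single genes of the kynurenine pathway, on which the compound acts, differed between R6/2 and WT mice. Ido1, which converts tryptophan to the precursor of kynurenine, fell from 23.0 ± 2.98 CPM in WT striatum (n = 8) to 8.20 ± 1.42 CPM (n = 7; log2 -1.49 ± 0.23, adjusted p = 1.01e-05). In the cortex it fell from 0.464 ± 0.182 to 0.131 ± 0.134 CPM (-1.98 ± 0.41, adjusted p = 0.000399). Its paralogue Ido2 fell by 0.67 ± 0.14 in striatum and 0.78 ± 0.14 in cortex, and the aminotransferase Kyat3 by 0.48 ± 0.09 and 0.41 ± 0.11. The cortical Kyat3 call was lost with the run tag as a covariate (-0.32, adjusted p = 0.0877). Afmid, the formamidase that releases kynurenine, rose by 1.20 ± 0.18 and 1.03 ± 0.13, and Tdo2, a further entry enzyme, by 0.86 ± 0.19 in the cortex, while it was not called in the striatum (-0.04 ± 0.16). Kmo, the compound's target, averaged 0.207 ± 0.200 CPM in WT, 0.191 ± 0.329 in vehicle and 0.270 ± 0.226 in treated striatum, and 0.128 ± 0.0611, 0.142 ± 0.0466 and 0.115 ± 0.0608 CPM in the cortex. Like Kynu, Haao, Aadat and Acmsd it lay under the expression filter and was not tested. The vehicle striatum mean rests on replicate 2, which held 0.934 CPM, and was 0.0669 CPM without it. The WT mean was 0.140 CPM without replicate 5, at 0.675 CPM. Treated striatal libraries were spread widely too, from 0.0288 to 0.654 CPM. These untested means therefore do not show a rise of Kmo with treatment. The 8 tested pathway genes were 1 higher and 3 lower in the striatum and 2 higher and 3 lower in the cortex by both adjustments, and the list was not called (adjusted p = 0.421 and 0.873). Qprt (-0.59 ± 0.27, adjusted p = 0.0749), Kyat1 (0.07 ± 0.07) and Got2 (-0.02 ± 0.04) were not called in the striatum, but Qprt passed without vehicle replicate 4 (adjusted p = 0.045). On log2 FPKM plus 0.1, where the median of all genes moved by 0.122, limma called Kyat1 at 0.23 (adjusted p = 0.0117) and Got2 at 0.11 (adjusted p = 0.0240).

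Treatment with the KMO inhibitor left the R6/2 profile in place. Ryr1 averaged 9.57 ± 1.75 CPM in vehicle and 9.52 ± 1.90 CPM in treated striatum, against 142 in WT, Penk 358 ± 27.2 and 321 ± 80.4 CPM, and Drd2 71.0 ± 6.42 and 62.3 ± 19.3 CPM. Pathway genes upstream of the target were also alike: Ido1 was 8.20 ± 1.42 and 7.35 ± 2.89 CPM in the striatum, Afmid 3.65 ± 0.656 and 4.09 ± 0.878 CPM. Ido1 was 1.42 CPM in treated replicate 5, which was the lowest of its group for 21 of 23 projection neuron genes, and 8.20 ± 1.74 CPM in the other 7 treated libraries. In the cortex Sst was 37.8 ± 8.04 and 47.0 ± 8.80 CPM, Pou4f1 4.03 ± 0.863 and 3.66 ± 0.846 CPM. None of these differences between treated and vehicle mice was called.

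In the striatum 0 of 17394 genes were called between treated (n = 8) and vehicle (n = 7) R6/2 mice by edgeR, with 464 at an unadjusted p under 0.05 (2.67%). DESeq2, limma-voom and limma on FPKM plus 0.1 or 1 also called 0, with 467, 349, 438 and 411 at an unadjusted p under 0.05. The genes of smallest p, none called (adjusted p = 1), were the somatostatin receptor Sstr3 (log2 0.76 ± 0.25), Cybrd1 (0.57 ± 0.18), Mtfr1 (0.28 ± 0.08) and Tdp2 (0.18 ± 0.05), and Chp2 (-0.49 ± 0.14), Mro (-0.26 ± 0.07), Pcdhb14 (-0.25 ± 0.06) and Stab1 (-0.25 ± 0.08). In the cortex edgeR called 0 of 17484 genes, with 1015 at an unadjusted p under 0.05 (5.81%), and the other tools called 0 with 1065, 2038, 1018 and 1007. The smallest p there (adjusted p = 0.836) belonged to Galnt18 (0.26 ± 0.06), Fbxo6 (0.25 ± 0.06), Dnal4 (0.21 ± 0.05), Pld3 (0.17 ± 0.04), Mro (-0.38 ± 0.08), Smpdl3a (-0.22 ± 0.06), Pyurf (-0.19 ± 0.05) and Tmem33 (-0.15 ± 0.04). Treated cortical libraries carried tags L5 and L6 alone, which 3 vehicle libraries shared; within these tags 0 genes were called. The 95% interval of the drug effect lay within 1.5-fold in either direction for 14217 striatal genes (81.7%) and 14272 cortical genes (81.6%), and for 89.3% and 88.7% of the genes called in disease. The difference of the drug effect between tissues was called for 0 genes by edgeR, with 1258 at an unadjusted p under 0.05, and for 0 by DESeq2, limma-voom and limma on FPKM.

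Some gene groups stood together slightly below their vehicle level in treated mice. Myelin genes of the cortex had a median of -0.35, with Ermn at -0.39 ± 0.11, not called over all genes. Of the list 0 of 15 were called over all genes and 10 lower adjusted over the list alone (camera adjusted p = 2.74e-13; adjusted p = 0.793 with an estimated correlation). With 1 mean per animal the cortical myelin list differed by -0.34 (95% interval -0.63 to -0.05, exact permutation p = 0.026, adjusted over 30 lists 0.779; n = 8 and 7). The exact p was 0.0507 without treated replicate 1 and 0.0599 without vehicle replicate 2. Microglial genes of the striatum had a median of -0.15, with Cx3cr1 at -0.18 ± 0.06 (0 of 18 called by either adjustment; camera adjusted p = 5.55e-09, and adjusted p = 0.646 with an estimated correlation), and per animal differed by -0.15 (-0.29 to -0.02, exact p = 0.0309, adjusted 0.928). The exact p was 0.0519 to 0.0739 without any 1 of vehicle replicates 3, 5, 6 and 7 or treated replicates 4 and 5. Microglial genes of the cortex had a median of -0.09 (adjusted p = 0.0251; adjusted p = 0.957 with an estimated correlation; per animal exact p = 0.163). That call was lost without any 1 of vehicle replicates 1, 2 and 3 or treated replicates 4 and 6 (adjusted p 0.0575 to 0.421), and per animal the difference went from -0.09 to -0.06 without vehicle replicate 2.

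Striatal neuron lists were lower in treated than in vehicle striatum by the preset correlation, and these calls rested on treated replicate 5. That library stood apart, with Penk at 140.2 CPM, Drd2 at 19.5 CPM and 3.92% of counts on mitochondrial copies. The projection neuron list had a median of -0.15 (adjusted p = 8.67e-09), the indirect pathway list -0.17 (0.00165) and the direct pathway list -0.10 (0.0185). For each of them adjusted p = 0.838 with an estimated correlation, and 0 members were called by either adjustment. On log2 FPKM plus 0.1 the medians were -0.22, -0.25 and -0.12. Without treated replicate 5 the lists were not called (adjusted p = 0.0698, 0.0934 and 0.812), and the direct pathway list was not called without vehicle replicate 5 (0.0663). With 1 mean per animal the differences went from -0.22, -0.25 and -0.15 to -0.04, -0.08 and -0.01 without treated replicate 5.

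Other striatal lists called between treated and vehicle mice were also lost without single libraries. Immediate-early genes had a median of -0.06 (-0.14 on log2 FPKM plus 0.1; adjusted p = 0.00976), clock genes -0.05 (0.0185), endothelial genes -0.07 (0.00976) and genes of neighbouring regions 0.39 (0.00976). For each of these lists adjusted p = 0.838 with an estimated correlation, and 0 members were called by either adjustment. The immediate-early call was lost without any 1 of vehicle replicates 6 and 7 or treated replicate 7 (adjusted p 0.0659 to 0.0785). The clock call was lost without any 1 of vehicle replicates 3 and 4 or treated replicates 5, 6 and 7 (0.0534 to 0.767), and the endothelial call without any 1 of vehicle replicate 7 or treated replicates 3 and 5 (0.0588 to 0.0934). The call of neighbouring regions was lost without any 1 of vehicle replicate 4 or treated replicates 6 and 7 (0.0534 to 0.0593), and with 1 mean per animal the difference was 0.34, and 0.21 without treated replicate 5. For clock genes that difference went from -0.05 to -0.01 without treated replicate 5. For endothelial genes it went from -0.05 to -0.03 without any 1 of vehicle replicates 1 and 7 or treated replicate 5, and for immediate-early genes from -0.15 to -0.25 without treated replicate 1.

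The other 22 striatal and 28 cortical lists were not called between treated and vehicle mice with all libraries, and 10 of them were called without single libraries. In the striatum these were astrocyte genes (adjusted p = 0.0198 without treated replicate 5), oligodendrocyte precursors (0.0229 without vehicle and 0.0198 without treated replicate 5) and myelin genes (0.000183 without treated replicate 6). The others were glutamate receptors (0.0484 and 0.0213 without treated replicates 1 and 2), interferon genes (0.0499 without vehicle replicate 2, 0.00489 without treated replicate 4) and oxidative phosphorylation (0.0127 and 0.0432 without vehicle replicates 2 and 5). In the cortex without vehicle replicate 4 the direct pathway, indirect pathway and projection neuron lists of the striatum were called (0.0274, 0.00202 and 0.0392), and the indirect pathway list also without treated replicate 2 (0.0418). Endothelial genes were called there without any 1 of vehicle replicates 1 and 5 or treated replicates 2 and 6 (0.00987 to 0.0472). With 1 mean per animal 0 of 30 lists passed in either tissue after adjustment, and 1 in each tissue had an exact p under 0.05. Leaving out each R6/2 library in turn for these lists was chosen after seeing the data.

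**Figure D4:**
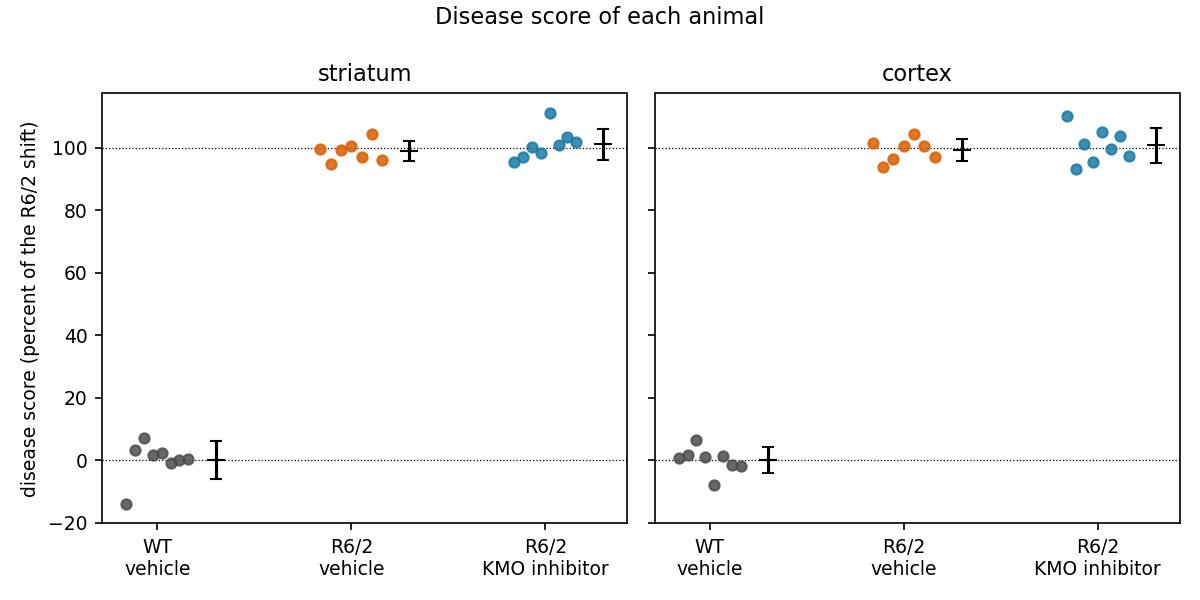
Disease score of each animal (vertical axis, percent of the R6/2 shift; 0 is the WT mean and about 100 the R6/2 mean) in the striatum and the cortex; points are animals, bars mean ± SD. Treated and vehicle R6/2 animals overlap at 101 ± 4.81 and 98.9 ± 3.22 in the striatum and at 101 ± 5.50 and 99.2 ± 3.57 in the cortex.

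Over the whole disease profile the score was 101 ± 4.81 in treated (n = 8) and 98.9 ± 3.22 in vehicle R6/2 striatum (n = 7), over 10044 genes. The difference was 2.19 points (95% interval -2.24 to 6.89, exact two-sided permutation p = 0.346). It was 0.821 without treated replicate 5, 1.13 without vehicle replicate 2 and at most 3.26, without treated replicate 1. In the cortex, over 8971 genes, the scores were 101 ± 5.50 and 99.2 ± 3.57, with a difference of 1.57 points (-3.68 to 6.87, exact p = 0.532), from 0.0701 without treated replicate 1 to 3.13 without treated replicate 2.

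Compared with WT, treated R6/2 mice showed the profile of vehicle R6/2 mice. Gpx6 was at -5.82 ± 0.24, Ryr1 at -3.89 ± 0.14 and Wt1 at 3.83 ± 0.24 in the striatum, and Pou4f1 at 5.26 ± 0.24, Pax2 at 3.65 ± 0.27 and Alox12b at -4.24 ± 0.18 in the cortex. In each tissue 13 of the 16 genes of largest change were those of vehicle mice. The others were AW551984 (1.94 ± 0.38), Vwa7 (-3.31 ± 0.23) and Ptpn7 (-3.69 ± 0.29) in the striatum and Zfhx2os (2.74 ± 0.52), Cd6 (-3.26 ± 0.33) and Rspo1 (-3.36 ± 0.18) in the cortex. Called genes numbered 9208 in the striatum (4832 higher, 4376 lower; 7450 and 2785 on log2 FPKM plus 0.1) and 8164 in the cortex (3988 and 4176; 5848 and 3084 on log2 FPKM plus 0.1). Treated and WT cortex shared no run tag, and with the tag as a covariate, which links them through vehicle libraries alone, 4062 genes were called. Vehicle and treated mice shared 7912 calls in the striatum, 4133 higher and 3779 lower, with 0 in opposite directions, against 1244 and 1070 that independent lists give and 0 in simulations of unchanged groups. In the cortex they shared 6662, 3205 higher and 3457 lower, against 856 and 946, and again 0 opposite and 0 simulated. With the WT libraries split between the comparisons the shared calls averaged 5794 and 4796.

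No gene differed in its disease or drug effect between females and males by edgeR. For the disease effect the interaction gave 0 genes in the striatum, with 773 at an unadjusted p under 0.05, and 0 in the cortex with 1097. The smallest adjusted p in the cortex was 0.0678. For the drug effect it gave 0 in the striatum, with 761, and 0 in the cortex with 2355, a share of 13.5% (smallest adjusted p = 0.196). DESeq2 called 1 gene for each interaction in the striatum, and 20 for disease and 67 for drug in the cortex; limma-voom called 1 for disease in the cortex and 0 for the others. Named after their values were seen, the single genes were Gm26527 for disease and Gm7887 for drug in the striatum (DESeq2) and Ptprn in the cortex (limma-voom). Gm26527 had a log2 interaction of 25.1 ± 5.08, too large to be a measured difference at this depth. Without vehicle replicate 1 edgeR called 27 genes for the drug effect by sex in the cortex, and without treated replicate 4 it called 1, Sh2d4b. Without vehicle replicate 5 it called 1 gene for disease by sex, Ptprn, named after its value was seen. Groups of 3 or 4 animals per sex found 65.2% and 56.1% of simulated 2-fold differences in the striatum and cortex.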

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

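The tests of treated striatal replicate 5 other than that of its disease score, both tests of spread between animals and the microglial test in the cortex were chosen after the results were seen; the other tests of this part were planned. Of 78 groups of libraries examined, 14 held a library far from the others. A rate of 1 in 20 would give 3.9, but that holds only for independent groups with normally distributed values. The genes examined came from the text, among them Prl and Gh, whose calls rested on single libraries. Several groups also flag the same library, so 3.9 is not a chance expectation for this set.

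Treated striatal replicate 5 had 140.2 CPM of Penk and 19.5 CPM of Drd2, against 56.5 CPM or more of Drd2 in the other 7 treated libraries, and 3.92% of counts on mitochondrial copies. It held the lowest value of the treated group for 21 of 23 striatal projection neuron genes. A mixed-up label is argued against, since its own animal's cortex library was its best match (r = 0.386 across genes, next 0.204), and so is low depth, since its 3.92% was the lowest and its total the highest of the group. Of 8 genes of neighbouring regions 1 was highest in this library, Trh, but 6 genes outside that list, chosen after their values were seen, were too (Irs4, Calb2, Gal, Slc17a6, Magel2, Zic4; Calb2 at 95.2 CPM against 14.9 CPM at most elsewhere), so RNA of another region may contribute and stays open. The same animal's cortex score was 101.3, the rank of 4 among 8 treated animals, so a stronger disease effect in this animal cannot be told apart either.

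The microglial list was lower in treated than in vehicle R6/2 striatum by 0.15 on the log2 scale. A single library is argued against: with any 1 of 15 left out the difference nearest to 0 was -0.12, although the exact p then reached 0.0739. The exact p was 0.0309 and 0.928 after adjustment over 30 lists, so spread between animals may account for it. In the cortex the difference was -0.094 (exact p = 0.163), which leaves an effect of the compound in both regions open.

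The myelin list was lower in treated than in vehicle R6/2 cortex by 0.34 on the log2 scale (exact p = 0.026, adjusted 0.779), so spread between animals may account for it. Among libraries with tags L5 and L6 the difference was -0.51 (8 treated and 3 vehicle; exact p = 0.0242), which argues against the run tag. By the plan, a WT range at least as large as the difference was to count for the amount of white matter in the piece. The 8 WT cortex libraries, which received no compound, ranged over 0.58, so the planned outcome was met. After this value was seen the reading was changed to open, since a range of 8 single animals exceeds most differences of 2 means. The amount of white matter therefore cannot be told apart. An effect of the compound stays open, untested.

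Other libraries stood far from their group. Mitochondrial copies held 6.16% in striatal vehicle replicate 5 and 8.85% in striatal WT replicate 1, whose disease score was -13.9. Kmo was at 0.934 CPM in striatal vehicle replicate 2 and 0.675 CPM in striatal WT replicate 5. These 2 libraries were also the highest of their groups for the thalamic marker Prkcd (33.6 and 175 CPM, TMM-scaled over all 46 libraries). In the cortex Prl was at 9.80 CPM in treated replicate 3, 0.884 CPM in vehicle replicate 2 and 104.7 CPM in WT replicate 8, and Gh at 0.684 CPM in vehicle replicate 2 and 44.6 CPM in WT replicate 8. The myelin list mean was 7.59 in striatal WT replicate 7.

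The disease effect differed between the tissues in 2862 genes by the interaction test. The tissues shared no run tag in WT or vehicle R6/2 mice, so differences that follow the tag cannot be told apart. Among the named genes the difference was 1.82 for Ipcef1, 1.46 for Phf21b, 0.80 for Nlk, 0.85 for Pak1 and 1.38 for Tcf19, and -1.93 for Cnr1, -0.75 for Acly, -1.06 for Pde1c, -1.16 for Grik2 and -2.14 for Onecut2. Of 30 splits of the animals 1, the real one, gave as many genes, and the highest other gave 0. A share of 1 in 30 is the smallest that 30 splits can give, so they argue against chance without excluding it. The other counts are not those of unchanged groups, since mixed groups keep the real difference as spread within them.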

How the results depend on the processing

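Leaving out both odd striatal libraries, the per-animal list means and leaving out R6/2 libraries in the drug lists were chosen after the data were seen. Total disease counts ranged over 7930 to 9664 genes in the striatum and 6545 to 8461 in the cortex under the alternatives. With 1 library left out they ranged over 8262 to 8750 and 7220 to 7647. With the replicate number as a block they were 8277 and 7351. The balance of directions was less stable. In the cortex 3753 genes were higher and 3959 lower in the main test, but 3946 and 3840 with DESeq2 size factors. On log2 FPKM plus 0.1 limma called 5469 higher and 2992 lower there. The drug comparisons gave 0 by edgeR (464 and 1015 at an unadjusted p under 0.05), and 0 in each of 12 alternatives per tissue, which include DESeq2, limma-voom and limma on FPKM, and in each of 15 leave-outs. The difference in score between treated and vehicle ranged over 0.627 to 4.41 and 0.0254 to 3.40 points. Treated against WT cortex gave 4062 with the run tag as a covariate, which leaves no shared tag between the groups. For disease by sex DESeq2 called 1 gene in the striatum and 20 in the cortex. There limma-voom called 1, the 2 groups alone 1 and FPKM plus 1 called 2. These 2 were Kdm5d and Uty, Y-linked genes that females lack, so they show no disease effect that differs between the sexes. With 1 library left out the count was 0 to 1. For drug by sex DESeq2 called 1 in the striatum and 67 in the cortex, FPKM plus 0.1 and plus 1 called 1 each, and leave-outs 0 to 27, the latter without vehicle replicate 1. Of 70 list calls 8 were kept with an estimated correlation, 2 of them for the developmental factors, whose tested members the expression filter decides, and of 10 drug list calls 0; without both odd libraries 6 drug lists were called, with per-animal means 0, and with 1 R6/2 library left out 7 to 13. Of 134 striatal and 123 cortical disease values of single genes 12 and 9 lost their call on FPKM plus 0.1, and 4 and 9 with the run tag. Over all fits with a single library left out, 4 and 11 of them lost their call in at least 1 fit. The list median went from -0.91 to -0.47 for striatal interneuron genes and from 0.99 to 0.60 for cortical interferon genes on FPKM plus 1. Got2 in the striatum was at 0.11 on FPKM plus 0.1 and 0.11 on FPKM plus 1 against -0.02, and was called there (limma adjusted p = 0.0240 and 0.0231). On log2 CPM without TMM scaling the median disease change of all genes moved by 0.125 in the striatum and 0.0846 in the cortex. On log2 FPKM plus 0.1 it moved by 0.122 and 0.0776. The shift toward higher calls on FPKM is thus of the size that leaving out TMM scaling gives. Apart from this shift and the tag, the cause of these changes was not tested.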

Other observations

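All tests of this part were planned except that the patterns themselves were noticed in these data. A set of genes differed between animals alike in striatum and cortex, whatever the genotype or treatment. After removal of group and sex, 158 of 18122 genes had a correlation above 0.9 between the tissues over 23 animals, against at most 1 in 100 shuffled pairings. Examples are Zfp990 (r = 0.987) and Cldn34c1 (r = 0.991). Inherited variants that segregate among the animals are a candidate explanation: the 80 pairs of such genes within 5 Mb had a median absolute correlation of 0.683, against 0.190 for pairs on different chromosomes (permutation p = 1e-04, the smallest that the permutations can give). Animals whose codes share the first part correlated at 0.412 over these genes (6 pairs), against -0.056 for other pairs (permutation p = 1e-04), so they may be relatives. Of the genes with a position 42.3% were pseudogenes, against 3.99% of all genes, so reads shared with parent genes stay open for that part.

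Genes near Gm12695 did not differ more often than others. Within 5 Mb on chromosome 4, 19 of 44 genes (43.2%) were called in the striatum, against 50.2% of the others (Fisher's exact p = 0.369). In the cortex it was 28.9% against 44.1% (exact p = 0.0496). No excess of calls near the insertion was seen. Since 50.2% and 44.1% of the other genes were called too, a few calls from linked sequence would hardly move these shares and stay open.

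Prl and Gh were highest in the cortex of 1 WT animal. Pomc, Cga, Tshb, Lhb and Pou1f1, pituitary genes, were all highest in that library too (5 of 5), with Pomc at 14.5 CPM. Tshb, Lhb and Pou1f1, at 0.284, 0.114 and 0.199 CPM, lay near the floor and carry little weight. The same animal's striatum was the highest striatal library for Prl (35.5 CPM, at most 6.05 elsewhere), Gh, Pomc and Cga, but not for Tshb, Lhb and Pou1f1. Pituitary tissue carried into the dissection is a candidate explanation.

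Genes enriched in 1 region were lower more often in that region when choice and test used different WT animals. The percent lower was 50.6 in the striatum against 19.8 in the cortex for striatal genes, and 49.5 against 20.4 for cortical genes. The smaller excess, 29.1 points, argues against regression to the mean as the whole cause.

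Other splits of the same animals were fitted for each count. In the striatum 1 of 100 splits, the real one, gave as many disease genes (8735, highest other 5415), treated against WT (9208, 6003) and shared calls (7912, 0). In the cortex 1 of 100 gave as many (7712, highest other 4686; 8164, 4760; 6662, 21), as for WT striatum against cortex (10708, 4036). A share of 1 in 100 is the smallest that 100 splits can give, so for these counts the splits argue against chance without excluding it. Where the real count is 0 every split gives at least as many, so the splits say nothing on chance. These were 100 of 100 for the drug effect (edgeR; highest other 2 in striatum and 166 in cortex), 100 for disease by sex (3 and 2), 100 for drug by sex (3 and 12) and 30 of 30 for tissue by drug (162). Any gene was called in 4 of 100 splits for the cortical drug effect and 3 of 30 for tissue by drug. The splits with 166 and 162 genes may reflect a structure of the samples, which was not tested.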
